A study of Mus musculus with 8 samples.

How the data were processed

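Total RNA from freshly isolated pancreatic tumour isografts of 8 mice was sequenced, 4 libraries labelled control and 4 labelled MEKi for 7 days of trametinib. Per the labels' protocols, RNA was extracted with TRIzol and column purification, samples above a set RNA integrity limit were kept, and strand-specific total RNA libraries were sequenced on a HiSeq instrument. Per the submitters' processing notes, STAR 2.5.3a, DESeq2 1.18.1 and the genome build GRCm38 were used. The annotation and the counting step are not given in the sources used here, so genes that share reads with near-identical copies are uncertain. The deposited values are on a log2 scale, variance-stabilised by the authors per the file name, and filtered by them in a way not given in the sources used here. The lowest value is 5.12 in every library. Inverting the transformation from that floor gave whole reads for 100% of the values in each library (within 0.01 of a whole number), so that depth and reads per gene could be read from the table. The variance-stabilised scale pulls genes with few reads together, so log2 differences understate their change.

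The table has 19431 rows. Of these, 32 name no gene and hold between 0.103% and 0.172% of the reads of a library, and they were left out. For 86 symbols with several rows the row with the highest mean was kept, which left 19129 genes, 19058 of them matched by symbol to the reference names. The lowest total of a tested gene was 25 reads over the 8 libraries. Coordinates are from GENCODE for GRCm38, counted from 1. Reads in tested genes ranged from 20090101 to 38569550 per library. Libraries were placed under their labels by title. The replicate numbers of both groups run from 1 to 4 but nothing in the labels ties a number to a shared litter, day or batch, and no batch or date was given.

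Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) without covariates, two-sided, with Benjamini-Hochberg adjustment over all 19129 genes and a threshold of 0.05. Gene lists, 48 in all and written before the data were examined together with the tests and most alternatives, were tested with camera at a preset correlation of 0.01, with adjustment over the 48 lists. Beside it stand camera with an estimated correlation, fry, and an exact permutation test of the mean list score over all 70 relabellings, whose smallest two-sided p is 0.0286. Of 653 list entries, 611 were measured, 1 of them through an older symbol. A list score is the mean value of its measured genes in a library. Genes named in the text are the 8 largest past the threshold in each direction with non-overlapping groups and a gene name other than a model (0 genes qualified), for each list described up to 3 genes past the threshold or else the gene with the smallest p, and 19 genes fixed beforehand. The other 2 genes fixed beforehand are not reported here. Other genes are named with the words that they were chosen after their values were seen. A list of prostate secretion genes was written after 2 of them had been seen among the smallest p-values. Principal components were taken from all genes, centred and not scaled. Library pairs were compared by the median squared deviation of reads from a shared ratio, in units of sampling noise, over genes with at least 20 reads in the pair. Intervals of differences are 95% intervals from limma.

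The gene test was tested on simulated data with the means and spreads of the 19129 genes and 200 changed genes. It recovered 70.9% of 55 genes changed by 1 on the log2 scale, 100% of 74 changed by 2 and 100% of 71 changed by 4, and called 10 of 18929 unchanged genes. The simulated values were independent, and many changed genes ease the adjusted threshold. The recovery therefore does not give the power of the real comparison, in which Sbp, at a log2 difference of -3.42, was not called (limma adjusted p = 0.108). In a simulation with independent genes, camera called 2 of 45 lists that were not shifted. The inversion returned all 2000 simulated counts exactly.

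The alternatives were robust moderation, no trend, quantile normalization, aligned medians, the 75% of genes with the highest mean, every row kept, a minimum absolute log2 difference of 1, array weights, limma voom on the recovered reads, the mean acinar score as a covariate, the replicate number as a block, each library left out in turn, and for the ERK and macrophage lists an estimated correlation, fry and the members of no other list. In all other alternatives the camera p-values of lists use the preset correlation, which counts genes that vary together as nearly independent. A correlation was estimated only with all libraries and no covariate. Leaving out both control libraries with high acinar values was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.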

Results

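RNA sequencing was carried out on pancreatic tumour isografts, tumours grown from transplanted mouse tumour material, taken from 8 mice. Libraries from 4 mice are labelled control and libraries from 4 mice are labelled MEKi, the latter for 7 days of trametinib, an inhibitor of the kinases MEK1 and MEK2 that activate ERK. What the control mice received is not given in the sources used here. Expression was analysed for 19129 genes on a log2-like, variance-stabilised scale, on which a difference of 1 is close to a doubling for abundant genes and more than a doubling for genes with few reads. Reads in these genes numbered 23004843, 31797960, 22243966 and 20090101 in control replicates 1 to 4. They numbered 27144478, 20182531, 29919922 and 38569550 in MEKi replicates 1 to 4. Values are given as mean ± SD with n = 4 libraries per label, and the spread is that between mice. No pair of libraries was close enough to be one library deposited again, since the closest pair, control 4 and MEKi 1, still differed by 4.4 times the sampling noise of the reads.

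The first comparison checked the drug label through genes that ERK signalling drives. Expression of these genes did not separate the libraries labelled MEKi from those labelled control, and high and low libraries were found under both labels. Dusp6, which encodes a phosphatase that dephosphorylates ERK and is switched on by ERK activity, had values of 12.19, 12.14, 9.31 and 9.24 in control replicates 1 to 4 and 8.88, 12.12, 12.20 and 11.01 in MEKi replicates 1 to 4. Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, followed with 9.82, 9.88, 7.66 and 7.20 in the control libraries and 7.25, 9.88, 9.43 and 9.04 in the MEKi libraries. Over the 20 genes of the ERK pathway output list, the mean was 10.02 ± 0.78 (SD, n = 4) under the control label and 10.10 ± 0.68 (SD, n = 4) under the MEKi label, a difference of 0.08. The direction expected of an inhibitor of this pathway was therefore not seen between the labels, and all differences below are between libraries labelled MEKi and libraries labelled control.

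**Figure D1:**
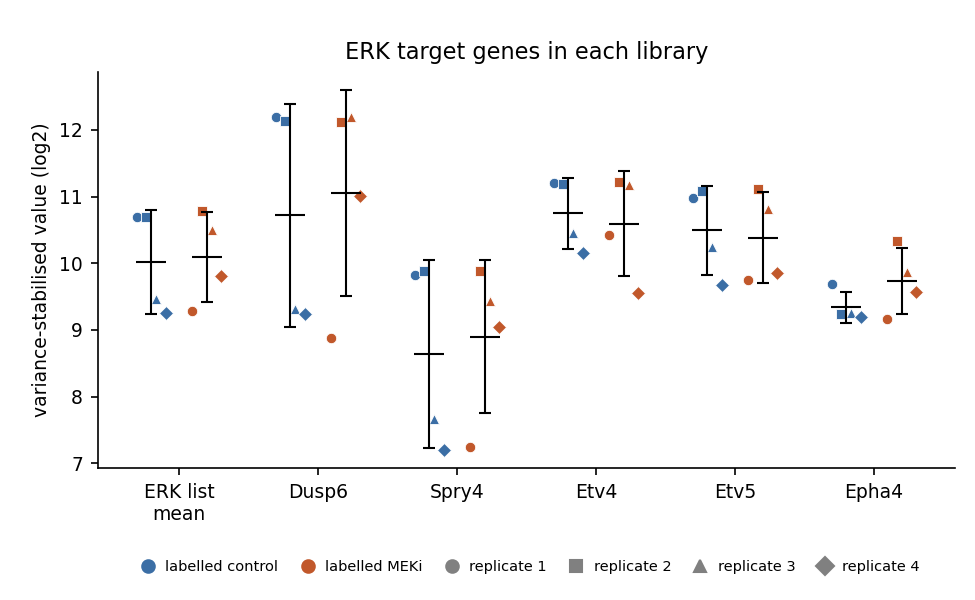
Variance-stabilised values (vertical axis, log2) of the ERK pathway output list mean and of 5 of its genes in each library, by label (colour) and replicate number (marker), with black bars for the mean and SD of 4 libraries. Dusp6 lies near 12 in control 1, control 2, MEKi 2 and MEKi 3, near 9 in control 3, control 4 and MEKi 1, and at 11.01 in MEKi 4.

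In the ERK pathway output list, 13 of the 20 genes had higher and 7 had lower means under the MEKi label. Limma called 0 of them over all genes tested and 0 adjusted over the list alone, with 0 at an unadjusted p under 0.05. The list did not differ from other genes by camera (adjusted p = 0.72) or in an exact permutation test of its mean score over 70 relabellings (two-sided p = 0.857). The log2 difference was 0.33 for Dusp6 (SE 0.90, 95% interval -1.70 to 2.36; chromosome 10, 99263231 to 99267489), 0.26 for Spry4 (interval -1.37 to 1.90; chromosome 18, 38586247 to 38601415). It was -0.15 for the transcription factor gene Etv4 (interval -1.01 to 0.71) and -0.11 for Etv5 (interval -0.98 to 0.76). Epha4, the list's gene with the smallest p, differed by 0.39 (SE 0.23, limma adjusted p = 1). The immediate early genes, mostly transcription factor genes and induced within minutes of growth factor signalling, had list means of 9.07 ± 0.59 and 9.08 ± 0.49 (camera adjusted p = 0.964). Their gene with the smallest p was Jund (8.32 ± 0.24 against 8.56 ± 0.25). Transcripts of the kinases of the pathway differed little: the log2 difference was 0.05 for Map2k1 (SE 0.17) and 0.04 for Map2k2 (SE 0.10), which encode the targets of trametinib, and 0.12 for Mapk3 (SE 0.11), which encodes an ERK kinase. Single libraries decided the list's test. The list was called higher by camera with the preset correlation without control 1 (adjusted p = 0.0256), control 2 (0.0418) or MEKi 1 (0.0106). These calls treat genes that vary together as nearly independent. With all libraries the correlation estimated between the list's genes was 0.76, and camera with it gave an adjusted p of 0.952. No correlation was estimated with a library left out. The mean difference turned to -0.11 without control 3, -0.18 without control 4, -0.16 without MEKi 2 and -0.06 without MEKi 3.

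Across the transcriptome, 1 gene was lower and 0 genes were higher in the libraries labelled MEKi. The lower gene, 9530002B09Rik, a protein-coding gene on chromosome 4 (122689275 to 122705129), is named although the rule for named genes leaves out such models, and was chosen after its values were seen. Its mean was 6.85 ± 0.34 (SD, n = 4) under the control label and 5.12 in all 4 MEKi libraries, the value that stands for 0 reads, a log2 difference of -1.73 (SE 0.16, limma adjusted p = 0.0235). As the 4 MEKi values all lie at this floor, the spread of the gene comes from its control libraries. The SE and the p-value may therefore be too small. Among the 19129 genes, 338 had an unadjusted p under 0.05 by limma, 89 higher and 249 lower. If no gene differed, 956 are expected on average, a number that can vary widely where genes are correlated. All 4 MEKi libraries lay above all 4 control libraries for 108 genes and below them for 134 genes, against 273 per direction by chance. The call did not survive without control 1 (adjusted p = 0.148), MEKi 1 (0.199), MEKi 2 (0.168), MEKi 3 (0.166) or MEKi 4 (0.18), with the acinar score as a covariate (0.0884) or with the replicate number as a block (0.255). The log2 difference stayed between -1.73 and -1.68 in all these fits. Without control 4, 2 genes were called lower.

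The study's title names tumour-infiltrating macrophages, and macrophage markers had lower mean values in the libraries labelled MEKi by a small amount. The 22 genes of the macrophage list averaged 10.43 ± 0.31 (SD, n = 4) under the control label and 10.11 ± 0.07 (SD, n = 4) under the MEKi label, a difference of -0.32, with 21 of 22 genes lower in sign. Control replicates 1 to 4 had list means of 10.43, 10.86, 10.28 and 10.14, and MEKi replicates 1 to 4 had 10.11, 10.09, 10.20 and 10.04. Values differed by -0.42 for Adgre1, which encodes the macrophage surface protein F4/80 (10.78 ± 0.33 against 10.36 ± 0.37), and by -0.67 for the mannose receptor gene Mrc1 (11.30 ± 0.80 against 10.63 ± 0.37). The difference was -0.25 for the lysosomal glycoprotein gene Cd68 (10.60 ± 0.33 against 10.35 ± 0.27) and -0.20 for the receptor gene Csf1r (12.19 ± 0.36 against 11.99 ± 0.14). Without control 2 these differences were -0.26 for Adgre1, -0.37 for Mrc1, -0.11 for Cd68 and -0.03 for Csf1r. Folr2, a folate receptor gene of tissue-resident macrophages, was the gene with the smallest p (6.71 ± 0.39 against 6.01 ± 0.45, SE of the difference 0.26). All 4 MEKi libraries lay below all control libraries, but barely. MEKi replicates 1 to 4 had 6.23, 6.23, 5.34 and 6.24, and the lowest control library, control 4, had 6.26. The Folr2 difference of -0.7 was -0.48 without MEKi 3.

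By camera with a preset correlation the macrophage list was lower (adjusted p = 1.49e-06), but the call was lost when the correlation between genes was estimated (adjusted p = 0.704 with an estimated correlation). An exact permutation test of the mean score gave a two-sided p of 0.0571, where 0.0286 is the smallest it can give. Limma called 0 of the 22 genes over all genes tested and 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05. Without control 2, the library with the highest macrophage list mean, the difference was -0.17. Acinar markers were also lower under the MEKi label, and with the acinar score as a covariate the macrophage difference was -0.25 (SE 0.20, exact permutation p = 0.257 over 70 relabellings, camera adjusted p = 0.000205 with the preset correlation).

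Other myeloid groups were lower in part. The alternatively activated macrophage list averaged 9.81 ± 0.33 against 9.39 ± 0.20 with 10 of 13 genes lower in sign (camera adjusted p = 0.0148, adjusted p = 0.704 with an estimated correlation). The mean difference of this list was -0.43 but the median over its genes was -0.06. Its gene with the smallest p was Retnla, which encodes a resistin-like protein induced by interleukin 4 (7.98 ± 0.46 against 6.74 ± 0.82, log2 difference -1.24, SE 0.39, limma adjusted p = 1). The myeloid growth factor and chemokine list differed by -0.27 with 19 of 23 genes lower in sign (camera adjusted p = 0.0119, adjusted p = 0.708 with an estimated correlation), led by the chemokine gene Ccl8 (10.79 ± 0.57 against 9.78 ± 0.45). Csf1, the main macrophage growth factor gene, had 10.96 ± 0.25 against 10.77 ± 0.38 and Ccl2 had 8.41 ± 0.86 against 8.22 ± 0.52. Neutrophil genes averaged 8.92 ± 0.12 against 8.55 ± 0.93 with 11 of 13 lower in sign (camera adjusted p = 0.00305, adjusted p = 0.704 with an estimated correlation), including the receptor gene Csf3r at 10.90 ± 0.06 against 10.31 ± 0.68. The neutrophil list means were 8.60, 8.54, 9.67 and 7.40 in MEKi replicates 1 to 4, against 8.83 to 9.09 in the control libraries. The mean difference was 0.02 without MEKi 4 (adjusted p = 0.26) and -0.74 without MEKi 3 (adjusted p = 3.5e-10), against -0.37 with all libraries. It was -0.64 with the acinar covariate (0.000143) and -0.23 with array weights (0.0118). These p-values are from camera with the preset correlation, while the correlation estimated between the neutrophil genes with all libraries was 0.47. The alternatively activated macrophage call also ended without control 2 (0.239, mean difference -0.33) or MEKi 4 (0.254, -0.33) and with the acinar covariate (0.233, mean difference -0.27). The growth factor and chemokine call ended without control 1 (0.27, mean difference -0.15), control 2 (0.375, -0.11), MEKi 1 (0.146, -0.20) or MEKi 4 (0.253, -0.17). Monocyte genes differed by -0.26, with F13a1 at 9.97 ± 0.83 against 8.84 ± 1.05, and dendritic cell genes by 0.15, with Clec10a at 8.61 ± 0.32 against 8.20 ± 0.57. The F13a1 difference of -1.13 was -0.61 without MEKi 3, the lowest library at 7.29, and -0.40 with the acinar covariate. Neither list was called (camera adjusted p = 0.0863 and 0.17). In these 5 myeloid lists limma called 0 genes over all genes tested and 0 adjusted over the list alone, with at most 1 per list at an unadjusted p under 0.05.

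**Figure D2:**
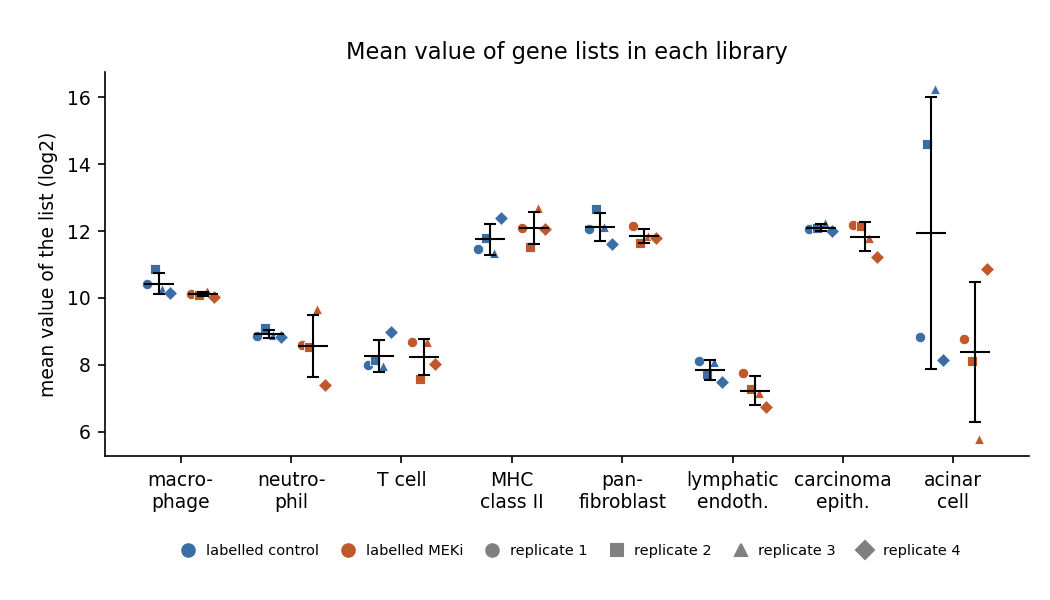
Mean value (vertical axis, log2) of 8 gene lists in each library, by label (colour) and replicate number (marker), with black bars for the mean and SD of 4 libraries. The macrophage list spans 10.14 to 10.86 in the control libraries and 10.04 to 10.20 in the MEKi libraries, and the acinar list spans 8.13 to 16.24 and 5.79 to 10.88.

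Lymphocyte markers showed no common direction, while antigen presentation genes had higher means under the MEKi label. T cell genes averaged 8.27 ± 0.47 and 8.24 ± 0.54 (camera adjusted p = 0.777). Cd3e, a chain of the T cell receptor complex, lay at 8.35 ± 0.48 against 8.17 ± 0.55, Cd8a at 9.90 ± 0.78 against 9.57 ± 1.09, and Cd4 at 8.33 ± 0.57 against 9.05 ± 0.70. The NK and cytotoxic lymphocyte list differed by -0.03 (camera adjusted p = 0.777), and its gene with the smallest p was the granzyme gene Gzmb (8.51 ± 0.38 against 7.75 ± 0.83). All 10 MHC class II presentation genes were higher in sign, with list means of 11.75 ± 0.47 and 12.09 ± 0.49 (camera adjusted p = 0.00305, adjusted p = 0.708 with an estimated correlation). Their transactivator gene Ciita had 10.26 ± 0.56 against 10.84 ± 0.52. B and plasma cell genes were higher in sign for all 12 measured members, at 7.13 ± 0.48 against 7.52 ± 0.81 (camera adjusted p = 0.00311, adjusted p = 0.708 with an estimated correlation). The complement receptor gene Cr2 lay at 5.97 ± 0.54 against 6.71 ± 0.91, with MEKi 3 at 8.05, and its difference of 0.73 was 0.28 without that library. Of the interferon response list, 17 of 22 genes were higher in sign (9.77 ± 0.44 against 9.96 ± 0.24, camera adjusted p = 0.00643, adjusted p = 0.805 with an estimated correlation). The guanylate-binding protein gene Gbp3 lay at 11.26 ± 0.63 against 11.81 ± 0.52. MHC class I genes averaged 11.75 ± 0.49 and 11.89 ± 0.52 (camera adjusted p = 0.138), with the peptide-loading gene Tapbp at 12.43 ± 0.29 against 12.79 ± 0.45.

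In these lymphocyte and presentation lists limma called 0 genes over all genes tested and 0 adjusted over the list alone, with 0 at an unadjusted p under 0.05. The MHC class II difference of 0.34 was no longer called without control 1 (camera adjusted p = 0.072, mean difference 0.24), control 3 (0.0825, 0.21) or MEKi 3 (0.209, 0.14) and with the acinar covariate (0.72, 0.08). It was 0.55 without control 4 (7.87e-08) and 0.53 without MEKi 2 (6.98e-06). The B and plasma cell difference of 0.39 was no longer called without control 1 (0.08, mean difference 0.24) or with the acinar covariate (0.234, mean difference 0.24). It was 0.03 without MEKi 3 (0.799) against 0.61 without control 2 (2.03e-05) and 0.68 without MEKi 4 (1.44e-07). The interferon call ended without MEKi 3 (0.286, mean difference 0.07) and turned without control 3 (mean difference -0.03) and with the acinar covariate (-0.11). The interferon difference was 0.29 without control 4 (1.06e-05). All these adjusted p-values are from camera with the preset correlation. With all libraries the correlation estimated between genes was 0.89 for the MHC class II list, 0.78 for the B and plasma cell list and 0.63 for the interferon list.

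Among stromal and vessel markers, the lymphatic endothelium, fibroblast and mesothelial lists were lower in mean under the MEKi label, while the myofibroblastic and pericyte lists were not. The lymphatic endothelium list differed most. Its 6 measured genes were all lower in sign, at 7.84 ± 0.31 against 7.23 ± 0.42 (camera adjusted p = 0.000149, adjusted p = 0.704 with an estimated correlation). The call held without each library in turn. Pdpn, which encodes podoplanin and is a member of both this list and the pan-fibroblast list, had 9.12 ± 0.36 against 8.36 ± 0.63 (log2 difference -0.76, SE 0.31, limma adjusted p = 1). Pan-fibroblast genes averaged 12.12 ± 0.43 against 11.85 ± 0.21 with 11 of 13 lower in sign (camera adjusted p = 0.00922, adjusted p = 0.704 with an estimated correlation). The collagen gene Col1a1 had 14.85 ± 0.66 against 14.65 ± 0.38. Inflammatory fibroblast genes averaged 9.01 ± 0.43 against 8.66 ± 0.24 with 13 of 14 lower in sign (camera adjusted p = 0.00311, adjusted p = 0.704 with an estimated correlation). Pi16, a marker of adventitial fibroblasts, lay at 8.59 ± 0.45 against 7.66 ± 0.85. Myofibroblastic genes did not differ (11.09 ± 0.29 and 11.09 ± 0.21, camera adjusted p = 0.777), with the smooth muscle actin gene Acta2 at 12.43 ± 0.03 against 12.60 ± 0.16. Pericyte and smooth muscle genes averaged 9.45 ± 0.27 against 9.54 ± 0.27, with 6 of 9 higher in sign (camera adjusted p = 0.101). Endothelial genes differed by -0.16 (camera adjusted p = 0.0665), with Pecam1 at 10.52 ± 0.60 against 10.13 ± 0.33. Mesothelial genes were lower in sign for all 7 members, at 7.85 ± 0.33 against 7.50 ± 0.21 (camera adjusted p = 0.00305, adjusted p = 0.704 with an estimated correlation). Gpm6a lay at 6.59 ± 0.30 against 6.16 ± 0.27.

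The fibroblast and mesothelial calls ended without control 2. The camera adjusted p was then 0.636 for the pan-fibroblast list, 0.253 for the inflammatory fibroblast list and 0.0722 for the mesothelial list, with mean differences of -0.09, -0.16 and -0.21, against -0.27, -0.35 and -0.35 with all libraries. The pan-fibroblast call also ended without MEKi 2 (0.101, mean difference -0.20) and the inflammatory fibroblast call without MEKi 4 (0.0512, -0.26). With the acinar covariate the values of the 3 lists were 0.618, 0.0558 and 0.374, with mean differences of -0.07, -0.26 and -0.10. Without control 4 the 3 differences were larger, at -0.44, -0.50 and -0.46, and called. The mesothelial call ended as well among the 75% of genes with the highest mean (0.483, mean difference -0.18).

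Exocrine pancreas was present in very different amounts between tumours. The 18 measured acinar cell genes, digestive enzymes and their regulators, had list means of 8.83, 14.60, 16.24 and 8.13 in control replicates 1 to 4 and 8.77, 8.10, 5.79 and 10.88 in MEKi replicates 1 to 4. All 18 genes were lower in sign under the MEKi label, with a mean difference of -3.57 (11.95 ± 4.07 against 8.38 ± 2.10, SD, n = 4). The difference ranged from -4.84 without control 4 to -2.14 without control 3. The list was called by camera with a preset correlation (adjusted p = 1.25e-13, but adjusted p = 0.704 with an estimated correlation). The exact permutation test did not separate the labels (two-sided p = 0.171). Prss2, which encodes a trypsinogen and shares sequence with other trypsinogen genes, so that its reads are uncertain, ranged from 9.78 to 18.66 in the control libraries and from 5.93 to 12.63 in the MEKi libraries. Without control 2 and control 3, a setting chosen after the data were seen, the mean acinar difference was -0.10 (camera adjusted p = 0.883). Islet endocrine genes were lower in sign for all 12 members (7.54 ± 0.65 against 6.75 ± 1.09, camera adjusted p = 2.68e-05, adjusted p = 0.704 with an estimated correlation). The difference of this list was -0.79, against -0.46 without control 3 (camera adjusted p = 0.0224), -0.30 without MEKi 3 (0.0338) and -0.17 with the acinar covariate (0.664). The somatostatin gene Sst lay at 6.72 ± 0.53 against 5.91 ± 0.66. Carcinoma epithelium genes averaged 12.10 ± 0.10 against 11.84 ± 0.44 with 11 of 15 lower in sign (camera adjusted p = 0.0327, adjusted p = 0.704 with an estimated correlation). The tight junction gene Ocln had 10.03 ± 0.21 against 9.66 ± 0.43 and the duct keratin gene Krt19 had 14.67 ± 0.14 against 14.64 ± 0.30. The tumour suppressor gene Trp53 had 11.92 ± 0.10 against 11.74 ± 0.34. The epithelial difference of -0.26 was no longer called without control 2 (0.0785, mean difference -0.27), control 3 (0.093, -0.21), MEKi 3 (0.208, -0.25) or MEKi 4 (0.805, -0.06). It was not called either with quantile normalization (0.288, -0.19), among the 75% of genes with the highest mean (0.0503, -0.25), with array weights (0.381, -0.12) or with the acinar covariate (0.155, -0.28).

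Cell cycle lists differed by small amounts. S phase genes were lower in sign for all 16 members, at 10.74 ± 0.14 against 10.59 ± 0.33 (camera adjusted p = 0.00305, adjusted p = 0.782 with an estimated correlation). The replication helicase gene Mcm6 lay at 12.55 ± 0.16 against 12.33 ± 0.31. Genes of the G2 and M phases had 13 of 16 members higher in sign, at 10.46 ± 0.37 against 10.54 ± 0.25 (camera adjusted p = 0.152), and the proliferation marker Mki67 had 12.33 ± 0.29 against 12.58 ± 0.25 (log2 difference 0.25, SE 0.17, limma adjusted p = 1). The S phase difference of -0.15 was -0.02 without MEKi 4 (0.8), -0.08 without control 4 (0.169) and -0.02 with array weights (0.73), and was not called in these fits. It was -0.29 without MEKi 1 (1.1e-08) and -0.24 with the acinar covariate (0.000143). These p-values are from camera with the preset correlation, while the correlation estimated between the S phase genes with all libraries was 0.8. In the stromal, epithelial, acinar, islet and cell cycle lists limma called 0 genes over all genes tested and 0 adjusted over the list alone, with at most 2 per list at an unadjusted p under 0.05.

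Over all 48 lists, camera with a preset correlation called 21, 18 lower and 3 higher. With an estimated correlation it called 0 (lowest adjusted p = 0.704), fry called 0 (lowest adjusted p = 0.445), and the exact permutation test of the mean scores called 0 after adjustment (lowest adjusted p = 0.943).

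A small set of genes was read under the control label alone. Besides 9530002B09Rik, with 60, 38, 66 and 38 reads in control replicates 1 to 4, these were Sbp, the prostate spermine-binding protein gene (452, 211, 506 and 93 reads), and Pbsn, which encodes the prostate protein probasin (29, 9, 12 and 44 reads). They also included Msmb, the beta-microseminoprotein gene (29, 7, 8 and 26 reads), and Defb50, a beta-defensin gene (25, 11, 5 and 28 reads). Each had 0 reads in all 4 MEKi libraries. Against a floor of 3 reads over the 115816481 reads of the MEKi group, Sbp was at least 502-fold higher under the control label (chromosome 17, 23941672 to 23945607) and 9530002B09Rik at least 80.3-fold. Pbsn was at least 37.4-fold higher (chromosome X, 77837901 to 77853623), Msmb at least 27.8-fold (chromosome 14, 32142023 to 32158370) and Defb50 at least 27.4-fold (chromosome 8, 21823539 to 21831296). These bounds allow only for the counting error of the 0 reads under the MEKi label. They leave out the counting error of the control reads and the spread between mice, and the genes were chosen after their values were seen. On the variance-stabilised scale the limma adjusted p was 0.108 for Sbp (log2 difference -3.42, SE 0.41) and 0.596 for Pbsn, Msmb and Defb50. Of the 12 genes on the list of prostate secretion genes, 5 were measured: Sbp, Pbsn, Msmb, Defb50 and Tgm4. Tgm4, a transglutaminase gene of the prostate, had 55 reads under the control label and 70 under the MEKi label. Sbp passed without control 4 (limma adjusted p = 0.0353), and Pbsn (0.0245), Msmb (0.0222) and Defb50 (0.0222) passed without control 2 and control 3. The control libraries left out in these fits were those with the fewest reads of each gene. As all MEKi values lie at the floor, the spread of each gene comes from its control libraries, so these passes add no support.

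**Figure D3:**
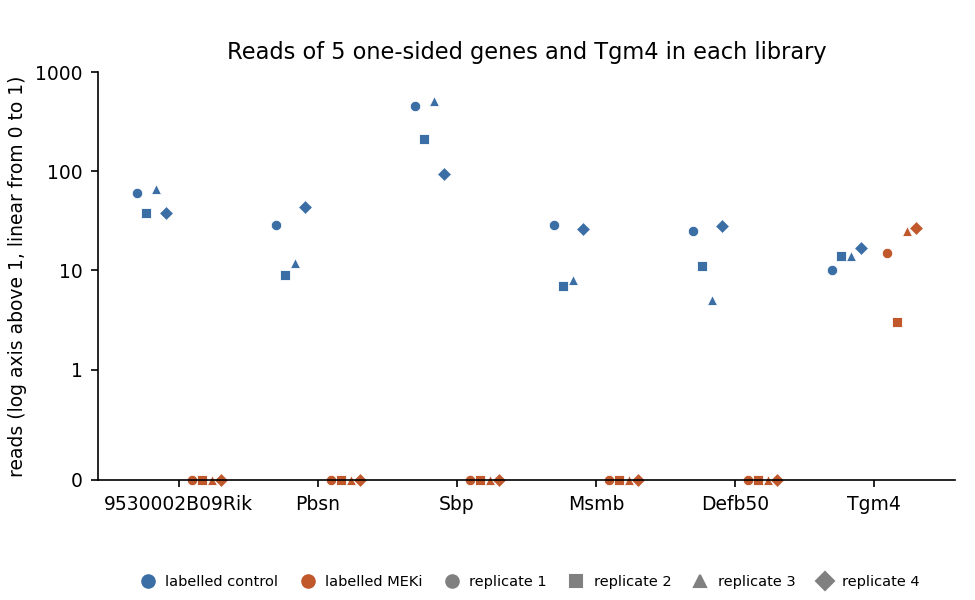
Reads (vertical axis, logarithmic above 1 and linear from 0 to 1) of 5 genes seen under the control label alone and of Tgm4 in each library, by label (colour) and replicate number (marker). The 5 genes have 5 to 506 reads in each control library and 0 in each MEKi library, while Tgm4 has 3 to 27 reads in all 8 libraries.

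The main axes of variation did not follow the label. The first principal component held 34.8% of the variance, with the acinar genes Pnlip, Cela2a, Cpb1, Try4, Cel and Ctrb1 at its positive end, and placed control 3 at 49.8 and control 2 at 24.2 against -43.6 for MEKi 3. The second held 26.5% and placed MEKi 4 at -47.0 and control 2 at 31.7. The third held 14.4%, had Dusp6, Spry4 and Egr1 at its positive end, and placed control 4 at -25.7 and MEKi 1 at -22.2 against 26.9 for MEKi 4. The fourth held 12.1%, with the insulin genes Ins1 and Ins2 at its negative end. The closest pairs crossed the labels, control 4 with MEKi 1 at 4.4 times the sampling noise and control 1 with MEKi 2 at 5.1 times, while the closest pair of one label, control 1 and control 2, lay at 10.4 times. The median distance was 18.8 times the sampling noise between libraries of the same label and 17.3 times between libraries of different labels.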

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

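All tests of explanations in this part were chosen after the results were seen. In 11 of 196 groups of 4 libraries, taken over the named genes, the list scores and the depth, the library at one end lay so far from the others that its gap exceeded Dixon's 95% critical share of the group's range. Chance gives about 5% of such groups. Control 4 stood apart for Cd3e (9.07 against a next value of 8.15, gap 0.929 of the range), Cd8a (11.06 against 9.58, gap 0.883), Tapbp (12.86 against 12.31, gap 0.895) and Gpm6a (6.14 against 6.72, gap 0.919). Control 3 stood apart for the islet endocrine list (8.51 against 7.24, gap 0.944), the ribosome biogenesis list (11.68 against 11.77, gap 0.95) and the immune checkpoint list (8.02 against 8.61, gap 0.858), and control 1 for Epha4 (9.69 against 9.25, gap 0.871). Among the MEKi libraries, MEKi 4 stood apart for Trp53 (11.23 against 11.87, gap 0.88) and MEKi 3 for Folr2 (5.34 against 6.23, gap 0.982) and the erythroid list (11.08 against 7.60, gap 0.847). No explanation was tested for these single libraries.

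The ERK target genes spanned the same range under both labels. An exchange of labels for some libraries of each group needs libraries out of place on both sides. Of the 16 pairs of a control and a MEKi library, the MEKi library was higher in ERK list score by over 0.5 in 5 and the control library in 4, but a range shared by both labels gives such pairs whatever its cause. An exchange of labels therefore stays open. Loss of the drug effect in some treated tumours with correct labels is argued against as the whole cause, since the control libraries spanned 1.44 in ERK list score, against 1.5 in the MEKi libraries. Acinar content is argued against as well, because in the 2 pairs of libraries of one label with acinar scores within 1 of each other the ERK list scores still differed by 1.44 and 1.5. Variation of ERK output between tumours that does not depend on the drug was not tested and stays open.

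The 5 genes read under the control label alone, and not under the MEKi label, follow the labels where the ERK targets do not. Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave as many genes with at least 3 reads in every library of one side and 0 on the other, and the highest count of any other split was 1 gene. This count was chosen because of these genes, so it describes them and does not test chance. Lower depth is argued against, as the MEKi libraries hold 28954120 reads on average and the control libraries 24284218. One outside source with a single gene mix is argued against because the mix of the 5 genes differed between control libraries (chi-square p = 1.28e-44, a test that treats reads as independent), with an Sbp to Pbsn ratio of 2.1 in control 4 and 42.2 in control 3. Several sources, or an effect of the drug on cells that express these genes, stay open, as the design ties both to the label.

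The macrophage list was the study's own subject and its call depended on the correlation assumed between genes. With an estimated correlation the adjusted p was 0.704, so a preset correlation below that of these genes could account for the call. Control 2 alone stays open as the cause, because without it the difference was -0.17, still below 0, while the MEKi libraries (10.04 to 10.20) overlapped the other control libraries (10.14 to 10.43). Acinar content stays open too, because with the acinar score as a covariate the list score differed by -0.25 (SE 0.20, exact permutation p = 0.257 over 70 relabellings), and the difference was -0.18 without control 2 and control 3. The macrophage difference thus remains a hypothesis that these 8 libraries do not settle.

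The number of genes and lists called was also set against other splits of the samples. For genes, 2 of the 35 splits called at least 1 gene, the real one with 1 and another with 755. Chance therefore cannot be excluded. The split with 755 genes set control 1, control 2, MEKi 2 and MEKi 3 against control 3, control 4, MEKi 1 and MEKi 4. It also divides the libraries by ERK list score, at 10.69, 10.69, 10.79 and 10.5 against 9.46, 9.25, 9.29 and 9.81. That split points to a structure of the samples that crosses the labels, so it is not a grouping without structure. For lists, 10 of the 35 splits, the real one included, called at least its 21 with a preset correlation. The highest other split called 30, so chance cannot be excluded there either.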

How the results depend on the processing

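The count of genes higher under the MEKi label was 0 under every alternative run. The count of genes lower was 0 among the 75% of genes with the highest mean, where the called gene was not tested. It was 0 with the acinar score as a covariate, 0 with the replicate block, 4 without both control libraries of high acinar content (chosen after seeing the data) and between 0 and 2 with each library left out in turn, against 1. Limma voom on the recovered reads called 1 gene, with 379 at an unadjusted p under 0.05, and 20 of the other 20 called lists. The replicate numbers showed no sign of pairing the libraries: the deviations of same-numbered libraries correlated at -0.33, 0.20, -0.46 and 0.02 across genes, and 1 of 8 libraries correlated best with its own number. These correlations run over all genes, so they cannot exclude a shared effect that is weaker than the other differences between tumours. The macrophage list stayed lower and past the threshold under the alternatives run on all genes and libraries, including the replicate block (adjusted p = 8.77e-08), and between 5.65e-09 and 0.00623 with each library left out, but not with an estimated correlation (0.704) or fry (0.981). The ERK pathway output list turned lower with array weights (adjusted p = 0.932) and with the acinar covariate (0.72). By camera with the preset correlation it ranged from 0.0106 to 0.743 with each library left out. With all libraries it was not called with an estimated correlation (0.952) or fry (0.981). The cause of these changes was not tested.

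Of the other 20 called lists, 3 kept their call without each library in turn, and of their 360 values under the alternatives 269 kept direction and side of the threshold. Turns in direction below are those of camera, relative to other genes. With the acinar covariate the acinar list itself turned, by construction (0.664), as did the interferon response list (0.175). Without both control libraries of high acinar content the pan-fibroblast list (0.883), the acinar list (0.883, mean difference still -0.10) and the interferon list (0.182) turned. With array weights the ribosome biogenesis list (0.952, mean difference 0.00) and the cholesterol synthesis list (0.828, still -0.01) turned, and with quantile normalization the cytosolic ribosomal protein list did (0.796). Left-out libraries moved the adjusted p from 0.00187 to 0.116 for ribosome biogenesis, 0.00535 to 0.607 for hypoxia, 2.53e-05 to 0.528 for cholesterol synthesis and 1.06e-05 to 0.369 for the interferon response, with turns in direction.

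Of the 481 values of 49 named genes under 10 alternatives other than leaving out 1 library, 468 kept direction and call. Log2 differences near 0 turned for Krt19 with quantile normalization (0.14), aligned medians (0), array weights (0.07) and without both high-acinar controls (0.01), for Dusp6 (-0.04) and Spry4 (-0.04) with array weights, and without those controls for Etv5 (0.06) and Col1a1 (0.18). With each library left out, differences ranged from -0.09 to 0.16 for Map2k1, -0.01 to 0.09 for Map2k2, -0.16 to 1.06 for Dusp6, -0.22 to 0.81 for Spry4, -0.36 to 0.19 for Etv4, -0.39 to 0.10 for Etv5, -0.43 to 0.07 for Ccl2, -0.35 to 0.06 for Cd3e, -0.69 to 0.05 for Cd8a, -0.49 to 0.05 for Col1a1, -0.10 to 0.11 for Krt19, -0.46 to 0.02 for Xist and -0.16 to 0.04 for Tgm4. Leaving out MEKi 4 moved the difference to -0.01 for Trp53, -0.27 for Csf3r, -0.14 for Clec10a, -0.46 for Gzmb, 0.46 for Cd4, -0.21 for Ocln and -0.10 for Mcm6, and leaving out MEKi 3 moved it to -0.48 for Pdpn. Leaving out control 2 moved it to -0.20 for Pecam1, control 3 to 0.33 for Gbp3 and MEKi 2 to 0.19 for Epha4. The Mki67 difference ranged from 0.12 without MEKi 3 to 0.37 without control 2. For Csf1 the range was -0.31 without MEKi 1 to -0.07 without MEKi 2, and for Tapbp 0.22 without MEKi 4 to 0.57 without MEKi 2. Limma voom gave larger differences for genes with few reads, such as -2.13 for Folr2 and -2.65 for Sst. Depth limits genes with few reads, whose values lie near the floor of 5.12.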

Other observations

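Genes of ribosome biogenesis, cholesterol synthesis, hypoxia and the cytosolic ribosome were lower in mean under the MEKi label by small amounts, and each call ended in several fits without 1 library. Ribosome biogenesis genes averaged 11.75 ± 0.04 (SD, n = 4) against 11.64 ± 0.34 with 13 of 14 lower in sign (camera adjusted p = 0.0327, adjusted p = 0.817 with an estimated correlation). The mean difference of -0.11 stayed at -0.11 without control 1 (0.116), control 2 (0.0949) or control 4 (0.102), though not called. It was 0.05 without MEKi 4 and 0.00 with array weights (0.952), but -0.19 without MEKi 1 (0.00341), -0.18 without MEKi 2 (0.00187) and -0.22 with the acinar covariate (0.000465). Cholesterol synthesis genes averaged 10.41 ± 0.11 against 10.27 ± 0.37 with 14 of 16 lower in sign (camera adjusted p = 0.0439, adjusted p = 0.817 with an estimated correlation). The mean difference of -0.14 was no longer called without control 2 (0.392, difference -0.08), control 4 (0.0692, -0.15), MEKi 3 (0.0844, -0.14) or MEKi 4 (0.528, 0.02). It was not called either without a trend in the variance (0.0532, -0.14), with array weights (0.828, -0.01) or with the acinar covariate (0.0731, -0.16). Without MEKi 1 it was -0.27 (2.53e-05). Hypoxia genes averaged 10.95 ± 0.15 against 10.75 ± 0.47 with 10 of 11 lower in sign (camera adjusted p = 0.0467, adjusted p = 0.805 with an estimated correlation). Without MEKi 3, whose list mean was 10.05, the mean difference was 0.03. The hypoxia difference of -0.20 kept most of its size but not its call without control 1 (0.231, difference -0.17), control 2 (0.178, -0.17) or control 3 (0.0825, -0.19), without a trend in the variance (0.0553, -0.20) and with array weights (0.148, -0.15). With the acinar covariate it was -0.03 (adjusted p = 1), and without MEKi 1 it was -0.31 (0.00535). Cytosolic ribosomal protein genes averaged 14.25 ± 0.10 against 14.16 ± 0.17 with 20 of 22 lower in sign (camera adjusted p = 0.00752, adjusted p = 0.805 with an estimated correlation). The mean difference of -0.09 turned to 0.02 with quantile normalization (0.796). It was no longer called without control 1 (0.0741, difference -0.08), control 2 (0.178, -0.06) or MEKi 4 (0.794, -0.02) or with array weights (0.129, -0.05). It was -0.14 without control 3 (9.25e-05), -0.16 without MEKi 2 (7.38e-05) and -0.16 with the acinar covariate (0.000205). Glycolysis genes (13.36 ± 0.26 against 13.25 ± 0.35, camera adjusted p = 0.101) and genes of lysosome and autophagy (11.65 ± 0.04 against 11.65 ± 0.08, camera adjusted p = 0.881) were not called.

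Matrix remodelling enzymes averaged 11.25 ± 0.36 against 10.98 ± 0.28 with 13 of 17 lower in sign (camera adjusted p = 0.0327, adjusted p = 0.704 with an estimated correlation). The matrix difference of -0.27 was no longer called without control 1 (0.116, difference -0.22), control 2 (0.392, -0.13), MEKi 3 (0.0716, -0.27) or MEKi 4 (0.253, -0.14). The same held with array weights (0.0733, -0.21) and with the acinar covariate (0.234, -0.24), while without control 4 it was -0.41 (0.000861). Mast cell and eosinophil genes averaged 7.17 ± 0.21 against 7.04 ± 0.28 with 7 of 9 lower in sign (camera adjusted p = 0.0467, adjusted p = 0.704 with an estimated correlation). Their difference of -0.13 was no longer called without control 2 (0.266, difference -0.04), control 4 (0.136, -0.14), MEKi 2 (0.325, -0.04) or MEKi 4 (0.253, -0.07). Nor was it called with quantile normalization (0.0639, -0.09), among the 75% of genes with the highest mean (0.723, -0.01), with array weights (0.128, -0.11) or with the acinar covariate (0.122, -0.13). It was -0.20 without control 1 (0.0145) and -0.25 without MEKi 3 (0.0105). Tumour subtype and state lists were not called, with classical subtype genes at 9.48 ± 0.28 against 9.37 ± 0.20 (camera adjusted p = 0.777), basal subtype genes at 7.91 ± 0.13 against 7.78 ± 0.30 (camera adjusted p = 0.138) and mesenchymal genes at 10.41 ± 0.22 against 10.41 ± 0.09 (camera adjusted p = 0.984). Receptor tyrosine kinase genes (10.33 ± 0.18 against 10.28 ± 0.13, camera adjusted p = 0.647), immune checkpoint genes (8.50 ± 0.32 against 8.56 ± 0.29, camera adjusted p = 0.73) and genes of classically activated macrophages (8.83 ± 0.33 against 8.72 ± 0.32, camera adjusted p = 0.642) were not called either. In the lists of this part limma called 0 genes over all genes tested and 0 adjusted over the list alone, with at most 1 per list at an unadjusted p under 0.05.

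Haemoglobin and other erythroid genes had a list mean of 11.08 in MEKi 3 and between 6.97 and 9.29 in the other libraries. Xist, the RNA that coats the inactive X chromosome, was abundant in all 8 libraries (12.65 ± 0.18 against 12.52 ± 0.67), including the control libraries in which the prostate genes Sbp and Pbsn were read. The other 4 members of its list, all genes of the Y chromosome, are not in the deposited table. That table keeps genes with totals as low as 25 reads, so a filter on reads alone would leave out only genes with few reads. The filter is not known, so the absence of these genes does not settle whether male cells were present.

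Of the remaining lists none was called by camera. The adjusted p was 0.26 for skeletal muscle, 0.73 for adipocyte, 0.76 for Schwann cell, 0.777 for erythroid, and 0.964 for cell cycle inhibitor genes. Mitochondrially encoded genes averaged 12.47 ± 0.14 against 12.61 ± 0.21 (camera adjusted p = 0.189). Canonical histone genes, transcripts that mostly lack a poly(A) tail, averaged 7.16 ± 0.04 against 7.06 ± 0.05 over 6 measured members (camera adjusted p = 0.0947). Their exact permutation p was 0.0286, the smallest it can give, and 0.943 after adjustment over the 48 lists. In these lists limma called 0 genes over all genes tested and 0 adjusted over the list alone, with at most 1 per list at an unadjusted p under 0.05.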
